A study of Saccharomyces cerevisiae with 45 samples.

How the data were processed

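Total RNA came from a budding yeast strain whose labelled genotype is mating type a with deletions in HIS3, LEU2, MET17 and URA3. Cells grew in rich medium (yeast extract, peptone, dextrose) at 25 °C and were shifted in a water bath to 37, 42 or 46 °C. Per the labels' protocols, RNA was column-purified and 150 ng of total RNA was amplified from its poly-A end and labelled with biotin for 3' expression arrays, which read the sequence near the end of a transcript. The deposited values are log2 intensities, 1 per probe set and array, which the authors summarised with RMA (background correction, quantile normalisation and median polish) through the affy package, per the submitters' processing notes. Versions of these tools and the genome build are not given in the sources used here. RMA normalises arrays to each other, so it removes any overall rise or fall in messenger RNA per cell, and it compresses changes near background.

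The table held 5900 probe sets on 45 arrays. Of these 137 were controls, 5498 had 1 gene symbol in the platform annotation, 0 had several and 265 others had none. All 5498 annotated probe sets matched a gene of the R64 reference annotation through the gene identifier, which updated 12 symbols. For 47 genes with several probe sets the one with the highest mean stood for the gene, which left 5449 genes. The values themselves showed 3 sets of arrays with separate distributions, so the arrays appear to have been normalised in 3 runs. Batches A863 and A705 had array medians of 10.20 to 10.26, A927 and A961 10.12 to 10.20, and P230 9.85 to 9.86. A floor of unspecific signal was taken in each set as the 95th percentile of 29 probe sets taken as without a target in this strain (array tags, tryptophan controls, URA3, LEU2 and MET17), at 5.33, 5.52 and 4.57. No probe set was removed for low signal. Identical values were found in 0 pairs of arrays. Probe sets of a second yeast, planned as the measure of unspecific signal, were not analysed here, and the probe sets without a target took their place.

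Groups, times and replicate numbers come from the sample titles. A mean per group was fitted to all 45 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 27 residual degrees of freedom), so that groups of 2 and of 3 arrays shared an estimate of the spread. Each time was compared with the 25 °C control of its own batch where there was one. The arrays at 37 °C 80 min were set against the control of batch A863, those labelled 42 °C 1 and 80 min against the control of batch A927, and those at 46 °C against the mean of both controls. The difference between temperatures was the change at 42 °C minus the change at 37 °C at the same time. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes in a comparison, and a gene counted as changed at an adjusted p under 0.05 and a log2 change of at least 1. No gene was excluded from any comparison for its level. The tests are unpaired.

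The design, 33 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule allowed the 6 largest rises and 6 largest falls among genes with standard names whose replicates did not overlap the control's, in 6 comparisons with 25 °C and, without the condition on overlap, in the 10 min difference between temperatures. It also allowed up to 4 called members of each list, any member of a list of 12 or fewer genes, and a fixed set of heat shock, stress and marker genes. A gene named in a comparison could be followed in another. Lists were tested against all other genes with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 33 lists, and again with a correlation estimated from the residuals. Replicates of batch A961 differed widely, so values with a correlation estimated without that batch are given beside some calls. Members were also counted with the adjustment taken over the list alone.

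The procedure was tested on simulated data for the same 5449 genes with 100 genes changed by 1.5 and 100 by 3 on the log2 scale. For 37 °C 10 min it recovered 93 and 96 of them with 4 false calls, for 42 °C 10 min 81 and 94 with 8, for 46 °C 10 min 86 and 99 with 4, and for the difference between temperatures at 10 min 72 and 88 with 5. Without batch A961 it recovered 100 and 100 for 42 °C 10 min with 0 false calls. The changed genes were drawn at random and given independent normal noise. Genes that respond to heat have a wider spread in the fit with batch A961, so for them the recovery may be lower. Alternatives covered the arrays that entered the fit, an intensity trend of the prior variance, 2 rescalings of the arrays, a filter at the floor, the replicate number as a block, array weights, the mean of a gene's probe sets, no minimum fold change, other controls, the batch as a random block, an estimated correlation in camera and each array left out in turn. The arrays measure levels relative to the other transcripts, and probe sets that share sequence between close paralogues may read both.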

Results

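The series followed messenger RNA in a laboratory strain of budding yeast (Saccharomyces cerevisiae, mating type a) moved from 25 °C to 37, 42 or 46 °C. The cells grew in rich medium before the shift to a water bath. RNA was hybridised to short-oligonucleotide expression arrays after 1, 3, 5, 7, 10, 15, 40 and 80 min at 37 °C, after 1, 3, 5, 10, 40 and 80 min at 42 °C, and after 10 and 30 min at 46 °C. In all, 45 arrays fell into 18 groups. The 25 °C control of batch A863 and every 37 °C time had 3 arrays. The 25 °C control of batch A927 and every 42 and 46 °C time had 2. The 37 °C times up to 40 min shared batch A863 with their control, and 42 °C at 3, 5, 10 and 40 min shared batch A927 with theirs. The remaining groups came from batches without a control, namely A705 (37 °C, 80 min), A961 (42 °C, 1 and 80 min) and P230 (46 °C). Values are log2 intensities of 5449 genes. The number of arrays limits their precision, and no label says whether replicates were separate cultures, so the p-values measure the spread between arrays, which may be technical.

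Outside batch A961, replicate arrays correlated at 0.991 to 0.999 over all probe sets, and 39 of 41 arrays lay closest to an array of their own group. The labelled genotype deletes URA3, LEU2 and MET17. On all arrays of the 37 °C series URA3 read 4.31 to 5.00, LEU2 4.85 to 5.73 and MET17 4.29 to 4.99. Over the same arrays 23 array tag and tryptophan control probe sets had a mean 95th percentile of 5.22 and reached 6.10, so the highest LEU2 value lay above that percentile. HIS3, also listed as deleted in the labels, read 10.87 to 12.38, and whether its probes lie outside the deleted part was not analysed here. Below, a gene is said to rise or fall when limma's adjusted p was under 0.05 and the change at least 2-fold. Changes are log2 differences from 25 °C, written with the standard error of the fit on all arrays. The disagreeing replicates of batch A961 (described with the 42 °C times) entered that fit, so the standard error of a responsive gene exceeds the spread between its own replicates. A difference of such a gene that did not pass the test is therefore not read as equal levels. A change with a group mean below the floor of unspecific signal of its arrays may be understated. This applies to HXT5 (batch A863 control), RRT5 and SPO19 (37 °C 10 min), YIG1 (37 °C 10 and 40 min) and ECM1 (42 °C 40 min), and to the genes described at the end as below the floor at 25 °C. A gene of a group of 5 or fewer that was named only after its values were seen is marked as such.

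**Figure D1:**
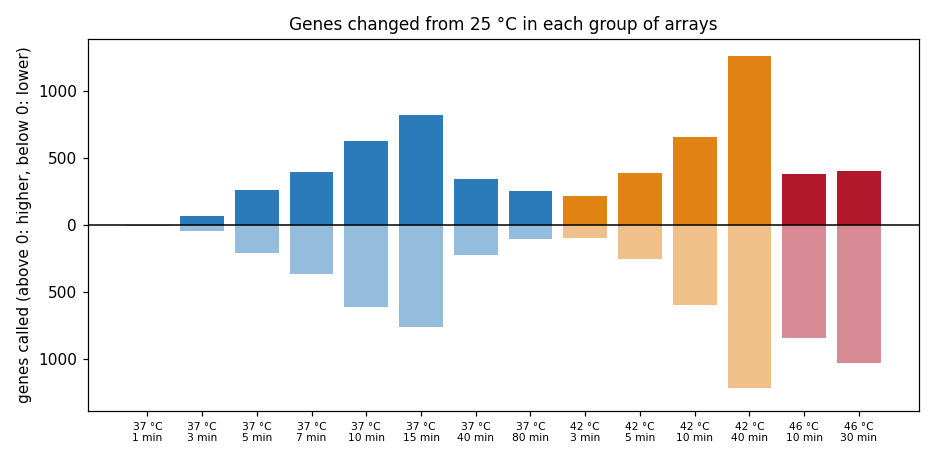
Number of genes called in each comparison with the 25 °C control, leaving out the arrays of batch A961. The vertical axis counts genes called higher (above 0, full colour) or lower (below 0, pale colour), and the horizontal axis gives temperature and time. At 37 °C the counts reached 817 and 763 at 15 min and were 345 and 224 at 40 min, while at 42 °C they reached 1262 and 1216 at 40 min.

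The 37 °C series asked how the response to a mild shift unfolds from its start. After 1 min 0 genes rose and 10 fell by limma's test, with 329 at an unadjusted p under 0.05. Among the fallen genes PRM7 fell by 2.34 ± 0.33 and ECM13 by 2.32 ± 0.30, both named after their values were seen. ECM13 also read lower in the unheated control of batch A927 than in that of A863, so its fall may depend on the control. The chaperone genes HSP42, HSP26 and SSA4 read 1.11 ± 0.38, 0.59 ± 1.36 and 0.22 ± 0.74, and none passed the test. At 3 min 67 genes rose and 42 fell. SSA4, a stress-inducible Hsp70, rose by 3.78 ± 0.74, the small heat shock protein gene HSP42 by 3.77 ± 0.38, the mitochondrial disaggregase gene HSP78 by 3.45 ± 0.52, and BTN2, which sequesters misfolded protein, by 2.72 ± 0.36. TSL1, a subunit of the trehalose synthase complex, rose by 3.24 ± 0.48. Of the Hsf1 core regulon, the chaperone genes that depend on the heat shock factor, 8 of 18 rose (9 adjusted over the list alone), and of the Msn2/4 general stress genes 13 of 40 (21), at adjusted p = 0.823 and 0.823 with an estimated correlation and 0.0121 and 0.0231 with one estimated without batch A961. Without the batch A961 arrays the count of changed genes at 3 min was 177.

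By 5 min 264 genes rose and 210 fell, and by 7 min 394 and 364. HSP26 rose by 7.01 ± 1.36, HSP12, a membrane-stabilising protein, by 5.55 ± 1.17, and CTT1, the cytosolic catalase, by 3.57 ± 0.56 at 5 min. At 3 min HSP26, HSP12 and CTT1 already read 3.25 ± 1.36, 2.44 ± 1.17 and 1.56 ± 0.56 without passing the test. Their calls at 5 min therefore do not date the start of their rise. Calls of lower genes for making ribosomes grew in number in the same interval, which does not date the start of their fall. Of the ribosome biogenesis list, 1 of 102 members fell at 3 min (RCL1, named after its value was seen), 29 at 5 min and 62 at 7 min. NOG2 fell by 3.81 ± 0.71, the helicase gene DBP7 by 3.34 ± 0.67 and TOD6, a repressor of ribosome biogenesis genes, by 3.40 ± 0.56 at 5 min. With p-values adjusted over the list alone, the biogenesis counts were 1, 29 and 68. Camera called the Hsf1, Msn2/4 and biogenesis lists at 5 min (adjusted p = 4.48e-11, 2.00e-15 and 3.16e-08), with adjusted p = 0.676, 0.676 and 0.951 with an estimated correlation, and 0.0238, 0.0282 and 0.00961 with an estimated correlation without batch A961.

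At 10 min 627 genes rose and 611 fell. The largest rises among genes whose replicates did not overlap were those of HSP26 (YBR072W, 8.02 ± 1.36, from 6.51 ± 0.10 to 14.54 ± 0.04, SD, n = 3 and 3), DDR2 (6.97 ± 1.13), SOL4 (6.81 ± 0.83), HSP12 (6.75 ± 1.17), TMA10 (6.75 ± 1.24) and RTC3 (6.05 ± 0.73). The largest falls were those of nucleolar and ribosome assembly factors, with UTP13 down by 6.52 ± 0.93, DBP3 by 6.49 ± 0.91, PUF6 by 5.91 ± 0.94, UTP25 by 5.78 ± 0.40, NSR1 by 5.74 ± 0.82 and RSA4 by 5.68 ± 0.76. Of the Hsf1 core regulon 14 of 18 rose with a median of 1.89. They included the disaggregase gene HSP104 (2.61 ± 0.24), the Hsp90 gene HSP82 (2.41 ± 0.30), its co-chaperone gene AHA1 (2.50 ± 0.39) and SIS1 (1.34 ± 0.22), an Hsp40. HSC82, which encodes the constitutive Hsp90, read 0.30 ± 0.08. Among the Msn2/4 genes 37 of 40 rose (median 3.42), and in trehalose and glycogen metabolism 16 of 17, with GPH1, glycogen phosphorylase, up by 5.61 ± 0.73 and PGM2 by 4.68 ± 0.52. In ribosome biogenesis 95 of 102 fell (median -3.56), and in RNA polymerase I and III 16 of 22, with RPA43 down by 4.86 ± 0.96 and RPA34 by 3.69 ± 0.64. Of the cytosolic ribosomal protein genes 2 of 127 fell, RPL22B by 2.04 ± 0.59 and RPS9A by 1.91 ± 0.44. Of the autophagy list 15 of 22 rose, including ATG41 (2.92 ± 0.73), and of the TCA cycle and respiratory chain list 16 of 43, including NDI1 (2.19 ± 0.29) and RIP1 (1.98 ± 0.22). Adjusted over the list alone, the risen Hsf1, Msn2/4, trehalose, autophagy and respiration genes numbered 14, 38, 16, 15 and 16, and the fallen biogenesis, polymerase and ribosomal protein genes 98, 17 and 1. Camera called 8 of the 33 lists higher and 6 lower, all with adjusted p = 0.636 or above with an estimated correlation. Without batch A961, 3 higher and 4 lower lists passed with an estimated correlation. Camera's adjusted p there was 0.0065 for autophagy, 0.0082 for respiration, 0.0065 for biogenesis and 0.0065 for polymerase. The Hsf1, Msn2/4 and trehalose lists did not pass (0.0662, 0.0656 and 0.135).

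At 15 min the counts were the highest of the 37 °C series, with 817 genes higher and 763 lower. Of 40 Msn2/4 genes 40 rose (median 4.15), as did 14 of 18 Hsf1 genes (median 2.06), and 101 of 102 biogenesis genes fell (median -4.51). DBP3 fell by 7.07 ± 0.91, RRP12 by 6.43 ± 0.75 and SAM1, an S-adenosylmethionine synthetase gene, by 4.83 ± 0.74. HXT5, a hexose transporter gene, rose by 6.16 ± 1.22, and polyubiquitin, encoded by UBI4, by 3.75 ± 0.58. Translation factors fell in 20 of 31 cases, with TIF4631 down by 3.37 ± 0.74, and aminoacyl-tRNA synthetases in 7 of 18. In the list of G1 cyclins and S-phase genes 7 of 22 fell, with CLN2 down by 2.67 ± 0.52 and RNR1, a ribonucleotide reductase gene, by 3.08 ± 0.41. The respiratory list had 24 of 43 members higher. When adjusted over the list alone, these counts were 40, 14, 101, 20, 7, 8 and 24, and all 7 lists had adjusted p = 0.52 or above with an estimated correlation. With one estimated without batch A961 their values were 0.0922, 0.101, 0.00799, 0.00935, 0.126, 0.0434 and 0.00799.

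After 40 min at 37 °C 345 genes were higher and 224 lower than at 25 °C. HSP26 (8.01 ± 1.36) and HSP12 (6.96 ± 1.17) rose most, followed by DDR2 (4.74 ± 1.13), SOL4 (4.54 ± 0.83), TMA10 (4.43 ± 1.24) and GPM2 (4.41 ± 1.13). The largest falls were those of the RNA helicase genes DBP2 (-4.27 ± 1.10) and DHR2 (-2.77 ± 0.69), the meiotic kinase gene SPS1 (-3.13 ± 0.33), YIG1 (-2.70 ± 0.17), the flavohaemoglobin gene YHB1 (-2.66 ± 0.55) and PRM7 (-2.65 ± 0.33). The direct test of 40 against 10 min called 334 genes higher and 288 lower. From 10 to 40 min the catalase gene CTT1 fell by 3.85 ± 0.56, HSP30, a plasma membrane protein, by 4.23 ± 1.12, BTN2 by 2.58 ± 0.36, HSP42 by 2.42 ± 0.38 and SSA4 by 1.89 ± 0.74. HSP26 and HSP12 differed by -0.01 ± 1.36 and 0.21 ± 1.17 between these times, and HSP104 by -0.76 ± 0.24. Ribosome biogenesis turned upward, with 67 of 102 genes higher at 40 than at 10 min, UTP13 by 5.52 ± 0.93 and DBP3 by 4.76 ± 0.91. The arginine genes ARG1 (3.33 ± 0.33) and ARG3 (2.71 ± 0.81) also rose. Among the Hsf1 and Msn2/4 genes 7 and 15 were lower at 40 than at 10 min. Adjusted over the list alone these 3 counts were 72, 7 and 15, with adjusted p = 0.937, 0.937 and 0.937 with an estimated correlation, and 0.0256, 0.18 and 0.281 with one estimated without batch A961.

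At 80 min, on arrays of batch A705 set against the control of batch A863, 256 genes were higher and 108 lower. HSP12 (6.48 ± 1.17) and HSP26 (6.18 ± 1.36) were still raised, as were HSP104 (1.47 ± 0.24), HSP82 (1.84 ± 0.30) and SSA1 (1.70 ± 0.29). ARG3 (3.69 ± 0.81), ARG1 (3.41 ± 0.33) and the methionine synthase gene MET6 (2.50 ± 0.09) were higher. BTN2 fell by 1.83 ± 0.36, its paralogue CUR1 by 2.01 ± 0.40 and RPN4, a regulator of proteasome genes, by 1.32 ± 0.27. Of the 102 biogenesis genes limma called 0 lower and 0 higher (0 and 0 adjusted over the list alone), at a median of -0.55. The 3' minus 5' signal of ACT1 was 0.92 ± 0.08 (SD, n = 3) in this group and 0.52 ± 0.01 in the control (n = 3), and the hybridisation controls changed by a median of -0.73. Batch and time cannot be told apart here. Against the control of batch A927 the count was 573, and BTN2 and CUR1 differed between the controls by -1.50 and -1.84 (A927 minus A863). RPN4 read 11.18 in the A927 control and 11.73 in the A863 control. Against the control of batch A927 the falls of BTN2, CUR1 and RPN4 would thus lie below 2-fold. Whether these genes fell, and by how much, depends on the control.

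**Figure D2:**
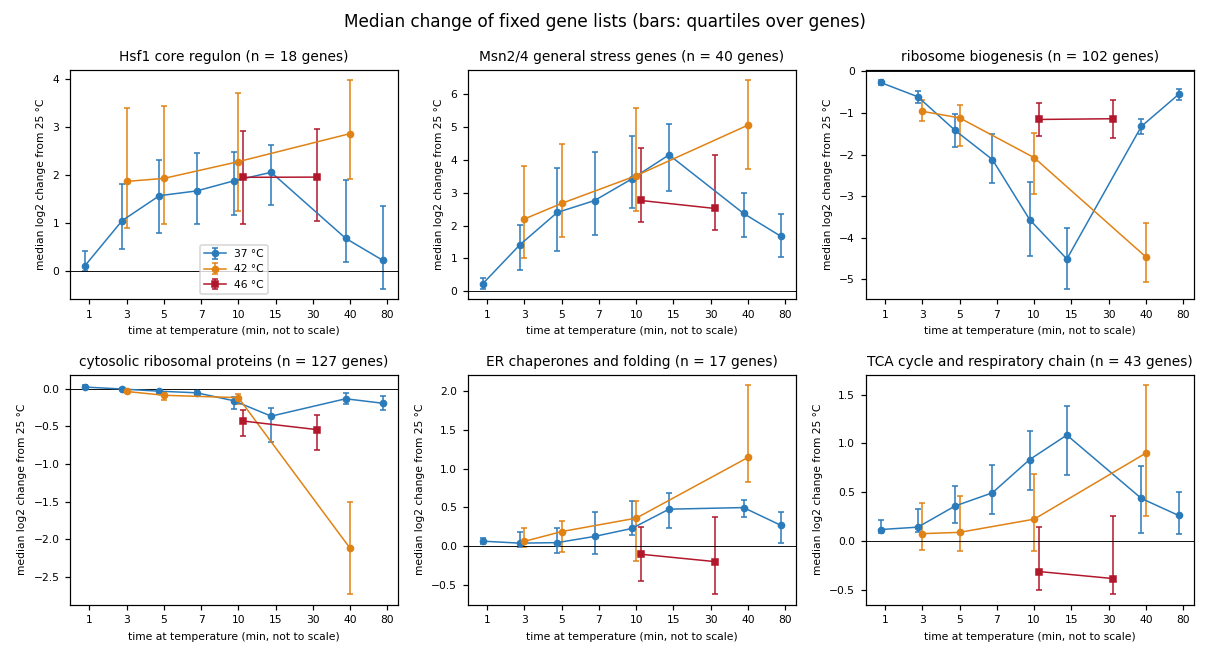
Median log2 change from 25 °C of 6 gene lists fixed in advance, against time at 37, 42 and 46 °C without batch A961. Points are medians over the genes of a list and bars are quartiles. At 37 °C the ribosome biogenesis median was -4.51 at 15 min and -1.32 at 40 min, and at 42 °C it was -2.07 at 10 min and -4.46 at 40 min, while the 46 °C medians include a shift of all genes by -0.39 and -0.38, and with centred arrays the sign turns for the ER list at both times and for the respiratory list at 10 min.

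At 42 °C named chaperone genes stood above the control after 3 min. HSP42 rose by 6.95 ± 0.46, HSP26 by 6.30 ± 1.66, HSP78 by 5.39 ± 0.64, SSA4 by 5.24 ± 0.91, BTN2 by 4.55 ± 0.44 and HSP104 by 3.42 ± 0.29. TSL1 rose by 5.76 ± 0.59 and GSY1, glycogen synthase, by 5.58 ± 0.52. In total 213 genes rose and 94 fell at 3 min, and 385 and 254 at 5 min. The Hsf1 regulon had 13 of 18 members higher at 3 min and 13 at 5 min, and the Msn2/4 list 23 and 30 of 40. Ribosome biogenesis had 1 of 102 lower at 3 min (DBP7) and 17 at 5 min, with DBP7 down by 3.49 ± 0.82 and NOG2 by 3.24 ± 0.87 at 5 min. The biogenesis medians were -0.96 and -1.12 at these times, so few calls do not mean that the list stood unchanged. With p-values adjusted over the list alone, the 3 min counts were 13, 24 and 0, with adjusted p = 0.227, 0.391 and 0.979 with an estimated correlation and 0.0125, 0.0256 and 0.0256 with one estimated without batch A961. At 5 min they were 13, 33 and 10, with 0.589, 0.589 and 0.948, and 0.0388, 0.0388 and 0.0388. Without batch A961 the counts of all changed genes were 492 at 3 min and 834 at 5 min.

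At 10 min 658 genes rose and 596 fell at 42 °C. HSP26 rose by 8.33 ± 1.66 (from 6.24 ± 0.01 to 14.57 ± 0.03, SD, n = 2 and 2), TMA10 by 7.78 ± 1.51, HSP30 by 7.44 ± 1.38, HSP42 by 7.32 ± 0.46, CYC7, a stress form of cytochrome c, by 6.85 ± 1.05 and GSY1 by 6.64 ± 0.52. The largest falls were those of REI1 (-5.64 ± 0.94), ECM1 (-4.98 ± 1.05), NSR1 (-4.83 ± 1.01), ALB1 (-4.79 ± 1.12), RPA43 (-4.75 ± 1.17) and IPI3 (-4.64 ± 0.76), which act in the assembly or export of ribosomal subunits or, for RPA43, in RNA polymerase I. Of the Hsf1 regulon 15 of 18 rose (median 2.28), with HSP82 up by 3.74 ± 0.37, SSA1 by 2.97 ± 0.36 and MDJ1, a mitochondrial Hsp40 gene, by 2.72 ± 0.46. Of the Msn2/4 list 36 of 40 rose (median 3.52), with CTT1 up by 5.54 ± 0.69, and of ribosome biogenesis 52 of 102 fell (median -2.07). RPN4 rose by 2.42 ± 0.33, and limma called 0 of 33 proteasome genes higher. The cell wall gene PRM5 rose by 2.64 ± 0.78 and the aspartyl protease gene YPS1 by 2.26 ± 0.53. Of the mitochondrial ribosomal protein genes 7 of 66 fell, MRPL37 by 1.83 ± 0.35 and MRPL20 by 1.45 ± 0.31. Adjusted over the list alone the Hsf1, Msn2/4, biogenesis, proteasome and mitochondrial ribosome counts were 15, 37, 52, 0 and 7. Camera called 7 lists higher and 5 lower, all with adjusted p = 0.641 or above with an estimated correlation. Estimated without batch A961, 2 higher and 2 lower lists passed.

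After 40 min at 42 °C 1262 genes were higher and 1216 lower, of 5449 tested. HSP26 rose by 8.88 ± 1.66, HSP30 by 8.41 ± 1.38, TMA10 by 8.41 ± 1.51, SOL4 by 8.19 ± 1.02, DDR2 by 8.00 ± 1.38 and CYC7 by 7.73 ± 1.05. The brightest risen gene read 15.12, where the brightest gene of the group read 15.15, so rises to such levels may be understated. The adenine deaminase gene AAH1 fell by 7.22 ± 1.30, NOP13 by 7.00 ± 1.28, ECM1 by 6.46 ± 1.05, NIP7 by 6.44 ± 1.30, RRS1 by 6.39 ± 1.12 and the CTP synthase gene URA7 by 6.32 ± 1.30. Genes of the translation machinery fell. Of the cytosolic ribosomal proteins 112 of 127 fell (median -2.12), RPS0B by 5.21 ± 1.20 and RPL27B by 4.50 ± 0.95, of ribosome biogenesis 101 of 102 (median -4.46), of translation factors 24 of 31 and of aminoacyl-tRNA synthetases 16 of 18. The Hsp70 gene SSB2, whose product works on the ribosome, fell by 4.06 ± 0.93. Of 40 Msn2/4 genes 40 rose (median 5.06), as did 15 of 18 of the Hsf1 regulon (median 2.87). HSF1 itself rose by 1.36 ± 0.37 and MSN2 by 1.08 ± 0.21. When adjusted over the list alone, these counts were 112, 101, 24, 16, 40 and 15. Their camera calls had adjusted p = 0.486 or above with an estimated correlation. With one estimated without batch A961 their values were 0.0167, 0.0167, 0.0167, 0.0829, 0.0829 and 0.0829. The 3' minus 5' signal of ACT1, which responds to RNA length, was 1.33 ± 0.07 (SD, n = 2) in this group and 0.75 ± 0.09 in its control (n = 2).

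Members of further lists were called at 42 °C and 40 min. Of the ER chaperones and folding factors 12 of 17 rose and 1, CNE1, fell, with SIL1 higher by 3.52 ± 0.78, MPD1 by 3.52 ± 0.68 and KAR2, the ER Hsp70 gene, by 1.08 ± 0.18. Proteasome genes rose in 8 of 33 cases, with RPN4 up by 3.03 ± 0.33 and RPN11 by 1.58 ± 0.33. Of the chaperonin TRiC and prefoldin 8 of 15 fell, PAC10 by 1.82 ± 0.52 and GIM3 by 1.46 ± 0.37. Mitotic cyclins and mitosis genes fell in 9 of 15 cases, CLB1 by 2.42 ± 0.59, and amino acid biosynthesis in 25 of 45, ILV3 by 4.36 ± 1.00 and ARO4 by 4.38 ± 1.22. Autophagy genes rose in 17 of 22 cases, ATG8 by 4.66 ± 0.79. Of the genes that mark a cells 6 of 7 fell, the transporter gene STE6 by 3.77 ± 0.78 and the pheromone receptor gene STE2 by 3.03 ± 0.62, while ASG7 rose by 3.13 ± 0.69. Among the 4 alpha-cell genes, markers of the other mating type, STE3 rose by 2.60 ± 0.64 and MF(ALPHA)1 read -0.38 ± 0.08. Of the meiosis and sporulation list 11 of 20 rose, IME2 by 3.20 ± 0.46 and SPO20 by 3.17 ± 0.79. With p-values adjusted over the list alone, the ER, proteasome, TRiC, mitosis, amino acid, autophagy, a-cell, alpha-cell and meiosis counts were 12, 8, 8, 9, 25, 17, 6, 1 and 11. Camera called all of these but the alpha-cell list, with adjusted p = 0.486 or above with an estimated correlation. When that was estimated without batch A961, the TRiC and autophagy lists passed (0.0343 and 0.0167) and the others did not.

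Set directly against 10 min, 457 genes were higher at 40 min and 600 lower. The 3' minus 5' signal of ACT1 was 0.82 ± 0.09 (SD, n = 2) at 10 min and 1.33 ± 0.07 (n = 2) at 40 min. This sign of RNA quality thus moved along with time in this comparison. Among chaperone genes of the cytosol HSP104 differed by 0.19 ± 0.29, HSP82 by 0.30 ± 0.37, SSA4 by 0.21 ± 0.91 and HSP42 by 0.11 ± 0.46, none past the test. Of the cytosolic ribosomal proteins 103 of 127 were lower at 40 min, where RPS0B fell by 4.89 ± 1.20, and of the synthetases 16 of 18. The ribosome biogenesis genes had 52 of 102 lower (52 adjusted over the list alone, adjusted p = 0.859 with an estimated correlation, 0.0179 with one estimated without batch A961). Of the ER list 10 of 17 were higher, SIL1 by 2.93 ± 0.78 and JEM1 by 2.51 ± 0.55, as was HAC1 (1.43 ± 0.32), which encodes the transcription factor of the unfolded protein response. With p-values adjusted over the list alone, the ribosomal protein, synthetase and ER counts were 110, 16 and 10, with adjusted p = 0.782, 0.782 and 0.859 with an estimated correlation, and 0.00425, 0.0397 and 0.0329 with an estimated correlation without batch A961. Leaving out replicate 2 of 42 °C 10 min brought the count of changed genes to 633 and leaving out replicate 2 of 42 °C 40 min to 676.

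The 4 arrays of batch A961 carry the labels 42 °C 1 min and 42 °C 80 min, and the arrays of each label disagreed. HSP26 read 6.14 and 15.15 on the arrays labelled 1 min and 15.18 and 6.40 on those labelled 80 min (replicates 1 and 2). The array labelled 1 min replicate 1 and that labelled 80 min replicate 2 correlated at 0.998 over all probe sets and had 7 genes 2-fold apart, and the other two 0.998 and 0. Within a label the correlations were 0.612 and 0.620, with 2670 and 2657 genes apart. The median change of the Hsf1 regulon from 25 °C was 0.56 and 2.81 on the arrays labelled 1 min and 2.79 and 0.59 on those labelled 80 min, and that of the cytosolic ribosomal proteins -0.06, -3.16, -3.17 and -0.04 in the same order. Fitted as labelled, limma called 1493 genes at 1 min and 1549 at 80 min against the control of batch A927, which were 23 and 58 when only these batches entered the fit. At 1 min the count was 2766 and 94 without its replicates 1 and 2, and 615 and 576 without those of the control. At 80 min it was 132 and 2800, and 791 and 747, in the same order. It called 0 genes between the labels, with 22 at an unadjusted p under 0.05, and 1218 and 1337 without replicates 1 and 2 of 1 min or 1201 and 1341 without those of 80 min. No direction is drawn from either label.

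**Figure D3:**
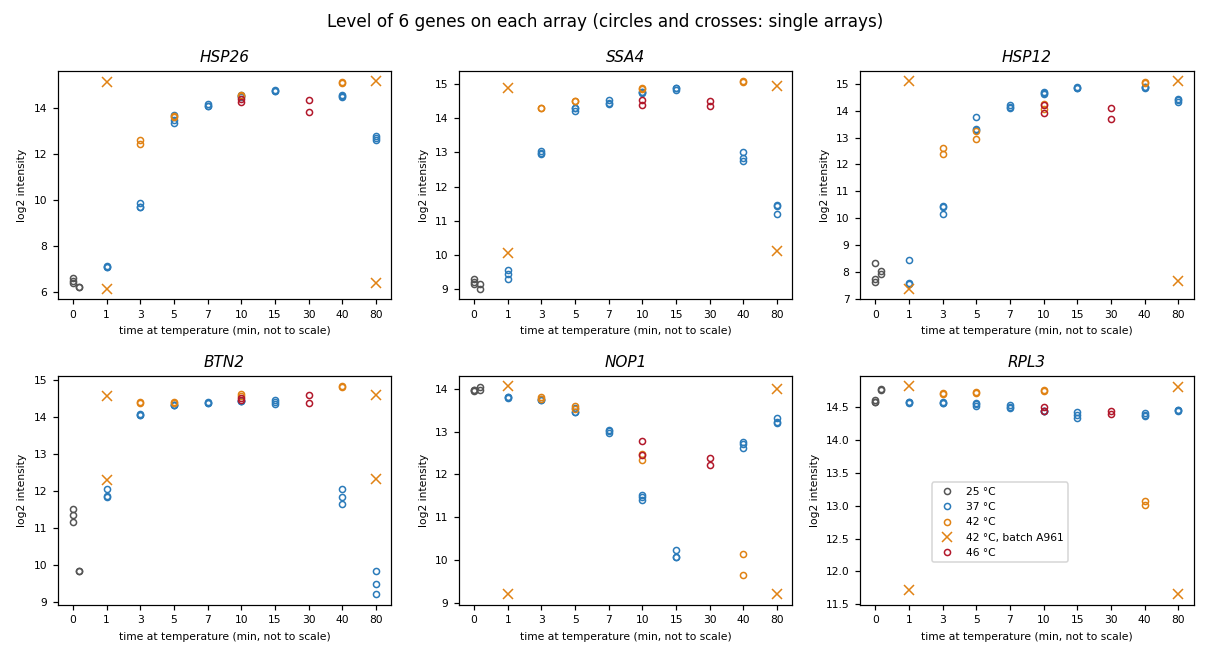
Log2 intensity of 6 genes (HSP26, SSA4, HSP12, BTN2, and, chosen after values were seen, the nucleolar gene NOP1 and the ribosomal protein gene RPL3) on every array, against time at temperature with 25 °C at 0. Circles are single arrays and crosses are the arrays of batch A961 at the time of their label. The 2 arrays labelled 1 min at 42 °C lie at 6.14 and 15.15 for HSP26, and those labelled 80 min at 15.18 and 6.40.

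Whether the response at 42 °C differed from that at 37 °C was tested as the difference between the changes at matched times. The arrays at 37 and 42 °C lay in different batches and in sets that appear separately normalised. Subtracting each control takes out a constant shift only, so temperature cannot be told apart from batch and normalisation in these tests. At 40 min 1860 genes differed, with 947 genes upward and 913 downward at 42 °C. HSP30 differed by 7.26 ± 1.78, GSY1 by 6.94 ± 0.68, ATG41 by 6.59 ± 1.16, the Hsp40 gene APJ1 by 5.81 ± 0.87, CTT1 by 5.50 ± 0.89 and RPN4 by 3.11 ± 0.43. Their levels at 40 min lay 5.55, 5.35, 4.79, 4.67, 4.68 and 2.55 apart (42 minus 37 °C). HSP26 and HSP12 differed by 0.87 ± 2.15 and 0.10 ± 1.85, neither past the test. Of the cytosolic ribosomal proteins 80 of 127 differed downward at 42 °C (median difference -1.99), with a difference between the changes of -4.81 ± 1.55 for RPS0B, and of ribosome biogenesis 68 of 102 (median -3.07), with -5.29 ± 1.68 for NIP7. Of the Msn2/4 and Hsf1 genes 27 of 40 and 12 of 18 differed upward. Adjusted over the list alone these counts were 88, 72, 28 and 12, with adjusted p = 0.688, 0.688, 0.688 and 0.688 with an estimated correlation, and 0.0256, 0.0328, 0.158 and 0.106 with one estimated without batch A961. The 3' minus 5' signal of ACT1 was 1.33 ± 0.07 (SD, n = 2) at 42 °C 40 min and 0.61 ± 0.03 (n = 3) at 37 °C 40 min, so this sign of RNA quality moved along with the temperature in this comparison.

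At 10 min 238 genes differed upward and 211 downward at 42 against 37 °C. The largest upward differences were those of RRT5 (4.48 ± 0.30), IRC10 (4.04 ± 1.19), YIG1 (3.91 ± 0.27), the peroxisomal catalase gene CTA1 (3.86 ± 0.35), SPO19 (3.74 ± 0.23) and ECM13 (3.72 ± 0.48). Downward, INH1, an inhibitor of the mitochondrial ATPase, differed by -2.74 ± 0.47, CTO1 by -2.53 ± 0.53, UIP4 by -2.45 ± 0.69, RAD50 by -2.07 ± 0.21, MRF1 by -2.03 ± 0.27 and YHP1 by -2.01 ± 0.72. In levels at 10 min (42 minus 37 °C) the 6 upward genes lay 1.66, 3.64, 3.72, 3.39, 1.64 and 2.20 apart and the 6 downward genes -0.18, -2.38, -2.48, -2.14, -2.11 and -2.23, in the same order. The 25 °C control of batch A927 minus that of A863 was -2.82 for RRT5, -2.10 for SPO19, -1.51 for ECM13 and 2.56 for INH1. CTA1 fell at 37 °C by 1.48 ± 0.22 and rose at 42 °C by 2.38 ± 0.27. The changes of ribosome biogenesis genes differed upward at this time (median difference 1.34, 3 of 102 genes past the test, namely RRP14, IMP4 and RCL1, named after their values were seen, 1 adjusted over the list alone, camera adjusted p = 2.06e-06, adjusted p = 0.932 with an estimated correlation, 0.0643 with one estimated without batch A961). For part of the genes the 25 °C controls differed as well. HSP42 differed by 2.80 ± 0.60, BTN2 by 1.67 ± 0.57, HSP82 by 1.33 ± 0.48 and HSP104 by 1.03 ± 0.38 between the changes, and their levels at 10 min lay 0.15, 0.17, 0.13 and -0.04 apart (42 minus 37 °C). In the control of batch A927 against A863 these genes fell by 2.66 ± 0.42, 1.50 ± 0.40, 1.20 ± 0.34 and 1.06 ± 0.27. Their levels at 10 min were 14.74, 14.42, 14.66 and 14.62 at 37 °C, where the brightest gene of the group read 15.02. Signals this close to the top may be saturated, so equal levels of chaperone genes in heated cells, here and at the other times and temperatures, do not exclude a difference in messenger RNA. Of the 449 genes 52 also differed between the controls, 44 of them with the opposite sign. The total was 759 without batch A961.

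At 3 min 39 genes differed and at 5 min 71, which were 145 and 183 without batch A961. The changes of HSP42 differed by 3.18 ± 0.60 at 3 min and 2.76 ± 0.60 at 5 min, those of GSY1 by 2.90 ± 0.68 and those of HSP104 by 1.41 ± 0.38 at 3 min. Their levels (42 minus 37 °C) lay 0.52 and 0.10 apart for HSP42, 1.31 for GSY1 and 0.34 for HSP104. Between the controls HSP42 fell by 2.66 ± 0.42, GSY1 by 1.59 ± 0.48 and HSP104 by 1.06 ± 0.27 (A927 against A863). Of the 39 genes at 3 min 20 differed between the controls, and of the 71 at 5 min 22. In 19 of these 20 and 22 of these 22 the sign was opposite to that of the control difference. A difference between the controls alone would give that sign. The count at 3 min was 22 without replicate 1 of 42 °C 3 min, 23 without its replicate 2 and 23 without replicate 1 of the control of batch A927. At 5 min 60 genes differed upward and 11 downward, and 50 and 19 after quantile normalisation. Across genes the changes at 37 and 42 °C correlated at 0.83 at 3 min, 0.87 at 5 min, 0.81 at 10 min and 0.65 at 40 min, with separate controls. Genes are not independent replicates, so no p is given. At 10 min 413 genes rose at both temperatures (75.7 for independent lists) and 343 fell at both (66.8).

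Without heat, the controls of batches A927 and A863 differed in 148 genes, 30 higher and 118 lower in A927. Chaperone genes were among the lower ones, with BTN2 at -1.50 ± 0.40 and HSP82 at -1.20 ± 0.34, and 5 of 18 Hsf1 genes passed the test, the others being HSP104, HSP42 and CUR1 (6 adjusted over the list alone, camera adjusted p = 0.00676, adjusted p = 0.965 with an estimated correlation, 0.159 with one estimated without batch A961). TSL1, the trehalose synthase subunit gene, was also lower, at -1.83 ± 0.54. CYC1, cytochrome c, was higher by 1.36 ± 0.28. Of the 30 higher genes 17 read below the floor in the A863 control, and the probe sets taken as without a target were higher by a median of 0.71 (up to 1.08), so background may carry part of these rises. The controls lie in separately normalised sets of arrays, so culture, batch and normalisation cannot be told apart.

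The 46 °C arrays asked how cells responded to a hotter shift, and no control shared their batch. Set against the mean of both controls, HSP26 rose by 7.95 ± 1.40 at 10 min and 7.74 ± 1.40 at 30 min, TMA10 by 6.96 ± 1.27 and 7.01 ± 1.27, HSP30 by 6.80 ± 1.16 and 6.71 ± 1.16, HSP12 by 6.11 ± 1.20 and 5.94 ± 1.20, HSP42 by 5.80 ± 0.39 and 5.69 ± 0.39, and PHM8, a nucleotidase gene, by 5.92 ± 0.98 and 6.11 ± 0.98. HSP104 rose by 2.79 ± 0.24 and 2.90 ± 0.24 and SSA4 by 5.32 ± 0.76 and 5.31 ± 0.76. REI1, a factor of ribosomal subunit maturation, fell by 5.59 ± 0.79 and 6.03 ± 0.79, ALB1 by 4.61 ± 0.94 and 4.36 ± 0.94, IPI1 by 4.37 ± 0.53 and 4.24 ± 0.53, CWC2 by 3.85 ± 0.34 and 3.89 ± 0.34, and the cyclin gene PCL1 by 3.80 ± 0.65 and 3.73 ± 0.65. DUS1 fell by 4.07 ± 0.47 at 10 min and SWC3 by 3.81 ± 0.14 at 30 min. The counts were 378 genes higher and 842 lower at 10 min, and 406 and 1028 at 30 min. Over all genes the median change was -0.39 at 10 min and -0.38 at 30 min, and falls are to be read against it. With each array centred on its median gene the split was 566 higher and 401 lower at 10 min and 644 and 527 at 30 min. After quantile normalisation it was 493 and 468, and 555 and 587. Called against each control separately and also after quantile normalisation were 250 higher and 348 lower genes at 10 min. Of the genes called at 10 and 30 min 63 and 67 differed between the controls. Against the control of batch A863 and then A927 the change of HSP42 was 4.47 and 7.13 at 10 min and 4.37 and 7.02 at 30 min, and that of HSP104 2.26 and 3.32, and 2.37 and 3.43. Temperature cannot be told apart from batch and normalisation in any of these tests.

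Among the gene groups at 46 °C and 10 min, 13 of 18 Hsf1 genes rose (median 1.96) and 34 of 40 Msn2/4 genes (median 2.76). Ribosome biogenesis had 22 of 102 genes lower (median -1.16, and -0.81 with centred arrays), and camera did not call it (adjusted p = 0.933). Of the cytosolic ribosomal proteins 3 of 127 fell (RPL22B, RPL41A and RPL9B, named after their values were seen), and of the mitochondrial ones 35 of 66, which were 12 with centred arrays and 10 after quantile normalisation. RSM22 fell by 2.60 ± 0.09 and RSM24 by 2.21 ± 0.12. RPN4 rose by 2.29 ± 0.28 and MET28, an activator of sulfur metabolism genes, by 3.91 ± 0.37. When adjusted over the list alone, the Hsf1, Msn2/4, biogenesis, cytosolic and mitochondrial ribosome counts were 13, 34, 15, 2 and 35. Camera called the Hsf1, Msn2/4 and mitochondrial lists, with adjusted p = 0.332, 0.332 and 0.332 with an estimated correlation, and 0.0307, 0.0307 and 0.449 with one estimated without batch A961.

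Between 10 and 30 min at 46 °C, in 1 batch, limma called 6 genes, all lower at 30 min, with 1087 at an unadjusted p under 0.05. HSP26 differed by -0.21 ± 1.66, SSA4 by -0.01 ± 0.91, HSP104 by 0.11 ± 0.29 and RPN4 by 0.17 ± 0.33. FUM1, the fumarase gene, fell by 1.04 ± 0.10, and the others were MGA1, PAU17, RCR1, RNQ1 and VPS27, named after their values were seen. The count was 1 and 31 without replicates 1 and 2 of 46 °C 10 min, 30 and 2 without replicates 1 and 2 of 30 min, and 0 when only this batch entered limma's fit, with 958 genes at an unadjusted p under 0.05. After quantile normalisation 1 gene was higher and 8 were lower.

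Set directly against 42 °C at the same 10 min, 46 °C had 114 genes higher and 538 lower, at a median over all genes of -0.31. With centred arrays the split was 230 and 245, and after quantile normalisation 215 and 252. HSP26 differed by -0.25 ± 1.66, HSP104 by -0.32 ± 0.29, HSP82 by -0.16 ± 0.37 and SSA4 by -0.42 ± 0.91, none past the test. RRP36, a ribosome biogenesis gene, stood 2.43 ± 0.72 higher at 46 °C, JJJ3 1.95 ± 0.41 and the peroxidase gene GPX2 2.16 ± 0.20. The lactate permease gene JEN1 fell by 2.50 ± 0.42, the cell wall regulator gene RLM1 by 2.26 ± 0.68 and RIP1, of the respiratory chain, by 2.15 ± 0.26. The probe sets taken as without a target in this strain differed by a median of -1.09 between these separately normalised arrays, so falls of dim genes are not read as falls of a transcript. Across genes the changes at 42 and 46 °C after 10 min correlated at 0.78 with separate controls. With a shared control the value was 0.82 (covariance 1.07), and part of it may come from that control. Simulated unchanged groups with a shared control gave 0.50 (covariance 0.00515). Sharing a control gives such a value for noise alone, so 0.50 is no baseline for 0.82 and nothing is drawn from it.

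Control probe sets were followed as well. The poly-A spike probe sets, for RNA added before labelling, changed by a median of 1.18 at 46 °C 10 min and 1.63 at 30 min, by 0.32 at 42 °C 10 min, 0.20 at 42 °C 40 min and -0.44 at 37 °C 40 min. The hybridisation controls changed by -0.03 and 0.12 at 46 °C, -0.34 at 37 °C 40 min and -0.73 at 37 °C 80 min, where the poly-A probe sets changed by -0.12. The probe sets taken as without a target in this strain changed by -0.40 at 42 °C 40 min and -0.92 at 46 °C 10 min. Probe sets for ribosomal RNA changed by 0.91 and 1.08 at 46 °C, 0.47 at 42 °C 40 min and 0.48 at 37 °C 80 min.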

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

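The tests of the arrays of batch A961, the scaling and messenger RNA tests of the spike probe sets and the background test of dim genes were chosen only after the result was seen. The tests of spike amount, neighbouring genes, cross-hybridisation and other splits were set before theirs.

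By limma's test the change from 25 °C differed between the 42 and 37 °C arrays in 39 genes at 3 min, 71 at 5 min, 449 at 10 min and 1860 at 40 min. Temperature cannot be told apart from batch and normalisation in these counts. Of the gene lists, ribosome biogenesis differed by a median of 1.34 at 10 min and -3.07 at 40 min, and at 40 min the cytosolic ribosomal proteins by -1.99, the Hsf1 regulon by 1.60 and the Msn2/4 genes by 2.64. Camera called these lists, all with adjusted p = 0.273 or above at 10 min and 0.461 or above at 40 min with an estimated correlation, while with one estimated without batch A961 the ribosomal protein and biogenesis lists passed at 40 min (0.0256 and 0.0328) and the Hsf1 and Msn2/4 lists did not (0.106 and 0.158), nor biogenesis at 10 min (0.0643). The levels of 1576 of the 1860 genes at 40 min lay 2-fold apart in the same direction, against 13 of 39 at 3 min. Among the 265 probe sets without a gene symbol, which no comparison used, 71 changed at 37 °C 15 min (53 higher, 18 lower) and 113 at 42 °C 40 min (88 higher, 25 lower).

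The arrays labelled 42 °C 1 min and 42 °C 80 min paired across their labels. Each correlated at 0.998 or more with an array of the other label, the pair near 25 °C had at most 190 genes 2-fold from 25 °C, where 42 °C 3 min had 492, and the other pair at least 2766, where 42 °C 10 min had 1399. These are values an exchange of labels between a 1 min and an 80 min array needs, and such an exchange is a candidate explanation. Degraded RNA on part of the arrays is argued against by an ACT1 3' minus 5' difference of at most 0.65 among the 4 arrays, below that of 17 other arrays. Cultures of a label that responded differently cannot be told apart from an exchange, since the arrays of a label correlated at 0.62 at most and only 2 arrays per label exist. On the array labelled 1 min replicate 2 the ribosomal protein median was -3.16, where 42 °C 3 min read -0.04 and 40 min -2.12. Such a culture would thus have passed the 40 min state after 1 min, but this rests on 1 array.

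The poly-A spike probe sets, outside the gene comparisons, rose at 46 °C by a median of 1.18 at 10 min and 1.63 at 30 min. An upward scaling of all probe sets on the separately processed arrays is argued against. At 10 min the hybridisation controls changed by -0.031 and the probe sets without a target by -0.92. The median gene changed by -0.39, so a scaling that differs with intensity is not excluded. A larger amount of spike stays open, because the gap between replicates was 0.68 of the difference between 30 and 10 min and no 25 °C array shares the batch. A lower share of messenger RNA in total RNA at 46 °C, the biological explanation the design offers, also stays open. At 42 °C 40 min the spikes changed by 0.20, within a gap between replicates of 0.28. Probe sets for ribosomal RNA changed by 0.91 and 1.08 at 46 °C. They also changed by 0.48 at 37 °C 80 min, where the spikes changed by -0.12, so they do not settle it.

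Of 154 genes below the floor at 25 °C in batch A927, 44 rose at 42 °C 40 min. A change in background is argued against by probe sets without a target, which changed by -0.40. Transcription read through from an upstream neighbour on the same strand stays open, as those neighbours differed in median level by 0.081 between genes that rose (18) and genes that did not (40), with a 95% bootstrap interval of -1.03 to 1.25 and a two-sided permutation p of 0.92. Cross-hybridisation with an abundant transcript also stays open: 34 of the 44 genes passed the level of 7 set beforehand as excluding it, but that bound was wrong, since the brightest risen transcript read 15.12 and a small share of its signal could exceed 7, and probe sequences were not analysed here. Induced transcription at 42 °C was not tested separately.

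For the comparisons of 3 with 3 arrays, 1 of the 10 splits, the real one, gave as many genes in each case when only those 6 arrays entered the fit. The real split gave 13 genes at 37 °C 1 min, 175 at 3 min, 628 at 5 min, 873 at 7 min, 1304 at 10 min, 1615 at 15 min, 779 at 40 min, 434 at 80 min and 710 between 40 and 10 min, and the highest of the other splits gave 0 each time. With 10 splits no share under 0.05 can be reached.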

How the results depend on the processing

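Fits without batch A961, the filter at the floor, the crossed block and the estimated correlation without batch A961 were chosen after the data were seen. Over the alternatives run for each, 3973 of 4078 values of the named genes stayed on the same side of the test. A further 101 lost the call, 4 gained it and 0 kept a call in the opposite direction. For the gene lists these numbers were 1197 of 1314, 104, 13 and 0, and 69 of the lost calls came with an estimated correlation on all arrays. Many named genes were picked for large or called changes in these data, and each array left out counted as an alternative. How often they kept their side of the test thus says little about all genes, whose counts moved as given below. A change of sign without a call in both settings was not counted as a turn. Such changes are therefore not excluded, and medians of some lists changed sign with centred arrays. Planned filters and a centring on probe sets of a second yeast were not run, as these probe sets were not analysed here. Signal over background limits dim genes, whose values lie near floors of 5.33, 5.52 and 4.57.

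Counts that moved by over 1.5 times follow, and their cause was not tested, except that dropping the minimum fold change adds smaller changes by construction. Without batch A961, in the fit of the own batches and with array weights, the counts were 177, 176 and 176 at 37 °C 3 min, 492, 491 and 492 at 42 °C 3 min, and for the differences between temperatures 145, 145 and 148 at 3 min, 183, 182 and 189 at 5 min, and 759, 759 and 766 at 10 min. Between 46 °C 30 and 10 min they were 13, 0 (limma, with 958 at an unadjusted p under 0.05) and 9. On the arrays labelled 42 °C 1 and 80 min the own-batch fit gave 23 and 58 genes and array weights 1 and 2. At 37 °C 80 min the control of batch A927 gave 573.

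With no minimum fold change the counts at 37 °C were 42, 512, 1620, 2275, 3069, 3654, 2214 and 1802 in order of time, at 42 °C 3, 5, 10 and 40 min 981, 1781, 2763 and 4349, on the arrays labelled 42 °C 1 and 80 min 3330 and 3367, at 46 °C 3191 and 3360, for the differences between temperatures 142, 300, 1253 and 3159, between the controls 707, between 40 and 10 min 2206 at 37 °C and 2762 at 42 °C, between 46 °C 30 and 10 min 539 and between 46 and 42 °C 2255.

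With 1 array left out, and a lone array assumed to vary like the other groups, the counts ran from 94 to 2766 for the label 42 °C 1 min, 132 to 2800 for 80 min, 1201 to 1341 between these labels, 22 to 31 for the difference between temperatures at 3 min, 633 to 741 between 42 °C 40 and 10 min, and 1 to 31 between 46 °C 30 and 10 min.

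Replicate numbers are shared between groups, but deviations with the same number correlated above 0.1 in 26 of 84 pairs in batch A863 and 4 of 20 in A927, and 10 of 24 and 6 of 10 arrays correlated best with their own number. In P230 the correlation was 0.58 and in A961 -0.996, each over 2 groups. With the replicate number as a block the count for the label 42 °C 1 min was 942, and every other count lay within 1.5 times, such as 1203 at 37 °C 10 min and 2458 at 42 °C 40 min. With the numbers of batch A961 crossed, limma called 0 genes between its labels, with 337 at an unadjusted p under 0.05.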

Other observations

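The genes below the floor were picked only after their values were seen, while the lists had been fixed. Members of further lists were called at 37 °C 15 min and 42 °C 40 min. Of the stationary phase and glucose-repressed genes 13 of 21 rose at 37 °C 15 min and 12 at 42 °C 40 min, where HXT5 rose by 7.67 ± 1.49. Of the oxidative stress defence genes 11 of 28 rose at 42 °C 40 min, PRX1, a mitochondrial peroxiredoxin gene, by 3.84 ± 0.74 and SRX1, sulfiredoxin, by 3.34 ± 0.71. Cell wall integrity genes rose in 11 of 26 cases, PIR3 by 4.53 ± 1.04 and PRM5 by 4.21 ± 0.78, and camera did not call that list (adjusted p = 0.0616). In ergosterol synthesis 7 of 24 genes fell, ERG13 by 2.01 ± 0.43 and ERG3 by 1.83 ± 0.40, while ERG28 rose by 1.54 ± 0.18. Among Hsp90 and its co-chaperones 6 of 14 rose and 3 fell, AHA1 up by 3.22 ± 0.48 and the phosphatase gene PPT1 down by 4.58 ± 1.02. In the cytosolic Hsp70 and Hsp40 system 9 of 23 rose, SSA3 by 5.48 ± 1.01, and 9 fell, JJJ1, which acts on the ribosome, by 3.55 ± 0.52. Adjusted over the list alone the counts at 42 °C 40 min were 12, 11, 11, 7, 6 and 3, and 9 and 9, and at 37 °C 15 min 13. Camera's adjusted p at 42 °C 40 min was 6.25e-04 for the stationary phase list, 0.0463 for oxidative stress, 0.0134 for ergosterol, 0.16 for Hsp90 and 0.526 for Hsp70. All these lists had adjusted p = 0.486 or above with an estimated correlation. With one estimated without batch A961 the values were 0.0923 for stationary phase, 0.225 for oxidative stress, 0.309 for cell wall, 0.196 for ergosterol, 0.157 for Hsp90 and 0.711 for Hsp70.

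Sulfur assimilation was mixed at 42 °C 40 min, with 8 of 22 genes higher, MET28 by 3.31 ± 0.44 and MET14 by 2.92 ± 0.58, and 3 lower, where SAM1 fell by 4.65 ± 0.90 and CYS4 by 1.74 ± 0.18. Of the mitochondrial chaperones and proteases 6 of 16 rose, HSP78 by 6.58 ± 0.64 and MDJ1 by 3.34 ± 0.46, and 1, the nucleotide exchange factor gene MGE1, fell by 1.26 ± 0.21. Of the ubiquitin and Cdc48 pathway 8 of 23 rose, UBI4 by 4.38 ± 0.70 and UFD1 by 2.13 ± 0.50. RNA polymerase I and III had 21 of 22 members lower, RPA43 by 5.96 ± 1.17 and RPA49 by 5.77 ± 1.20. In glycolysis 2 of 16 rose, TDH1 by 3.54 ± 0.76 and ENO1 by 1.07 ± 0.24. Adjusted over the list alone these counts were 8 and 3, 6 and 1, 8, 21 and 2. Camera's adjusted p was 0.0339, 0.0824, 0.0219, 3.15e-06 and 0.923, and adjusted p = 0.486, 0.486, 0.486, 0.486 and 0.955 with an estimated correlation. Estimated without batch A961 the polymerase list passed (0.0167) and the other 4 did not.

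Among genes below the floor at 25 °C that rose at 42 °C 40 min, named after their values were seen, ECM8 reached 11.09 and SIP4, a regulator of gluconeogenesis, 11.05. The spore wall genes OSW1 and LDS1 reached 9.80 and 10.39. Their changes at 37 °C 40 min were 0.19, 2.01, -0.19 and -0.21 in that order. Of the 11 risen members of the meiosis list, 1 had been below the floor.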
